A study of Mus musculus with 2 samples.

How the data were processed

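The data were 2 Visium libraries, each from 1 flash-frozen liver section (10 µm) of a male B6/129S mouse fed a high-fat diet for 10 weeks, 1 labelled Advillin-cre/ERT2 Control and 1 labelled Advillin-cre/ERT2 Casp3. Each deposited matrix held UMI counts per gene and spot, made by the authors with Space Ranger 2.0.0 per the file headers, against mm10 per the submitters' processing notes. The values were whole numbers with no normalization applied. The annotation version and the choice of spots were not given in the sources used here. Images and positions of spots were not used here. Both files listed the same 32285 genes, and 26259 of them matched a RefSeq table of assembly GRCm38.p6, the patch release behind mm10, by Ensembl identifier or symbol. Coordinates are from that table.

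Spots with fewer than 500 UMIs were left out, which removed 2 of 3668 Control and 49 of 3974 Casp3 spots. UMIs were summed over the spots of each library and scaled to counts per 1000000 UMIs (CPM). For each gene the log2 ratio of Casp3 to Control CPM was taken, with an exact conditional binomial 95% interval. With 1 library per group no test between groups was possible, and no p-value, standard error or count of changed genes is given. Genes with a mean of at least 20 CPM entered the count at 2-fold. A ratio to a library with 0 UMIs was computed against a floor of 3 counts in that library.

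Before the data were examined, 43 gene lists, the thresholds, the rule for named genes and most alternatives were fixed. A list was summarised by the median log2 ratio of its members with a mean of at least 5 CPM. This median was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of expression, and its interval was taken from 200 draws of the counts. A member counted as higher or lower at a log2 difference of at least 0.32. A percentile places a list among genes of these 2 libraries and is not a test between animals. Genes named were the 15 with the highest and the 15 with the lowest ratio at a mean of at least 20 CPM, the 3 members of each list with the largest absolute ratio, Avil and Casp3, and the 5 zonation genes with the largest difference in steepness at a mean of at least 50 CPM. In the liver regions, the 15 each way were taken after a further filter, given below and added after seeing the data. Other genes were picked after their values were seen, as said where they appear.

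Spots were ordered by the share of 6 pericentral genes among the UMIs of these and 6 periportal genes, and each library was divided into 5 equal ranges. Steepness was the log2 ratio of CPM in the most pericentral to that in the most periportal range, with a prior count of 0.5. The pericentral and periportal lists read along this order held no gene used in the ordering. Other lists were not filtered this way: the gluconeogenesis list held Sds and the lipid droplet list Hsd17b13, both used in the ordering. Shares of spots with a marker UMI were taken after thinning each spot once to 4000 UMIs, the 5th percentile of the shallower library rounded down to a multiple of 500. This kept 3514 Control and 3741 Casp3 spots and left out 152 and 184. Shares carry exact Clopper-Pearson intervals. Shares of Acta1, Krt13, Marco and Plin2 were added after seeing the data. Regions were found in each library alone by Leiden clustering (resolution 0.5, 15 neighbours, 20 components, 2000 variable genes, seed 1) and named by their leading genes.

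After seeing the data, 4 lists were added: 20 striated muscle, 10 squamous epithelium, 3 smooth muscle and 15 glucocorticoid-induced genes. Control regions with genes of the first 3 of these lists among their leading genes were left out to give the liver regions. Regions called led by hepatocytes are the liver regions not led by fixed markers of other cell types. They include regions without any leading gene. All planned values were also computed over all spots.

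Alternatives were totals without mitochondrially encoded genes, TMM factors, median-of-ratios factors, no UMI minimum, a stricter spot filter (3000 UMIs and under 30% mitochondrial UMIs), equal weight per spot, other gene floors, another choice of regions, another spot order, 3 ranges, pooled range limits, unthinned shares, a second seed, and other clustering resolutions (0.3 and 1). The closing section gives their effect. The calculations were tested on simulated data. In the liver-region comparison of 4394 genes, intervals held the true ratio for 95.5% of 200 changed and 95.6% of the unchanged genes. Those counts were drawn with counting error only, as the intervals assume. Of 20-member lists shifted by 0.5, 95% lay beyond the 97.5th percentile, and 6% of unshifted lists lay outside the central 95%. Genes in these lists varied independently, with a spread of 0.5. Members of a real list can vary together, so these rates do not carry over to the real lists. The steepness estimate had a slope of 0.995 on the truth over 3000 spots and 60 genes.

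Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. The last of these gave size factors only.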

Results

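RNA was counted spot by spot on 1 liver section from each of 2 male B6/129S mice fed a high-fat diet for 10 weeks. Visium slides capture RNA from a tissue section onto barcoded spots, so that 1 spot can hold several cells. The Control animal carried Advillin-cre/ERT2, a tamoxifen-inducible recombinase under the promoter of Avil, a gene of peripheral sensory neurons. The label of the Casp3 animal adds Casp3, the gene of a caspase that executes apoptosis, to the same driver, and how it was introduced was not given in the sources used here. Each group held 1 library, so no spread between animals could be measured, and every value below describes these 2 sections. The Control library held 64333583 UMIs over 3668 spots and the Casp3 library 63988621 UMIs over 3974 spots. After removal of 2 and 49 spots with under 500 UMIs, the median spot held 16786 UMIs and 3596 genes in Control, and 15920 UMIs and 3311 genes in Casp3. Mitochondrially encoded genes gave 5.26% of UMIs in Control and 3.61% in Casp3. Intervals are 95% intervals, exact for genes and shares and from 200 draws of the counts for medians of lists, and cover counting error only.

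Sensory neurons have their cell bodies outside the liver, so the targeted genes do not check the group labels. Avil (ENSMUSG00000025432), which encodes the actin-binding protein advillin, gave 8 UMIs in the whole Control library and 4 in Casp3. Casp3 (ENSMUSG00000031628) gave 632 and 611 UMIs, or 9.82 CPM (UMIs per 1000000, 9.07 to 10.6) and 9.55 CPM (8.81 to 10.3). The log2 ratio of Casp3 to Control for this gene was -0.04 (-0.20 to 0.12) and turned to 0.23 with TMM scaling, so its direction depended on the scaling. None of the 24 genes of neurons and Schwann cells reached a mean of 5 CPM.

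The liver lobule dominated both sections, and muscle and keratin transcripts were abundant in parts of the Control section. Clustering gave 9 regions in Control and 5 in Casp3. In Control, 627 spots were led by Slc1a2, Oat and Glul, genes of hepatocytes around the central vein. A further 587 spots were led by Aldh1b1, Etnppl and Sds, genes of the portal side. In Casp3, 642 spots were led by Slc1a2 and Glul and 1629 by Sds and Aldh1b1. Ighm, Slpi and Spp1, genes of B cells, epithelia and the matrix, led 359 Control spots, while Acta2, Hba-a1 and Mgp led 108 Casp3 spots and Msln, Slpi and Upk3b another 19. Haemoglobin genes led 172 Control spots. Among genes with at least 50 CPM in the region, 2 Control regions of 677 and 660 spots and 1 Casp3 region of 1527 spots had none as much as 2-fold above the rest.

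Regions 6, 7 and 9 of Control held 584 spots (15.9%) and 9.14% of its UMIs, and were led by Myh8, Krt13 and Krt4, by Myl2, Myh7 and Fabp3, and by Tnnt2, Myh11 and Cnn1. The 20 striated muscle genes summed to 90244 CPM in region 6 and 79235 CPM in region 7, where mitochondrially encoded genes took 26.9% of UMIs. The same genes summed to 449 CPM in the other Control regions and to 3.08 CPM in Casp3. Acta1, skeletal muscle actin, was found in 34.4% of Control spots and in 1 of 3741 Casp3 spots after thinning to 4000 UMIs. Krt13, a keratin of stratified epithelium, was found in 12.1% of Control spots and in 0 of 3741 Casp3 spots, which allows a share of up to 0.0802% at 3 counts of the total and 0.0986% by the exact interval. The 15 genes with the lowest Casp3 to Control ratio over all spots were all muscle or keratin genes. Among them, Krt13, Myh1, Myh2, Myh8 and Tcap had 0 UMIs in Casp3 and were at least 3847-, 11791-, 3273-, 5308- and 5941-fold lower there, with a floor of 3 counts in that library. Comparisons below are therefore given for the liver regions, which leave out Control regions 6, 7 and 9 (3082 Control spots with 58452406 UMIs, and all 3925 Casp3 spots). This restriction was chosen after seeing the data, and values over all spots are given beside it for some lists and genes.

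**Figure D1:**
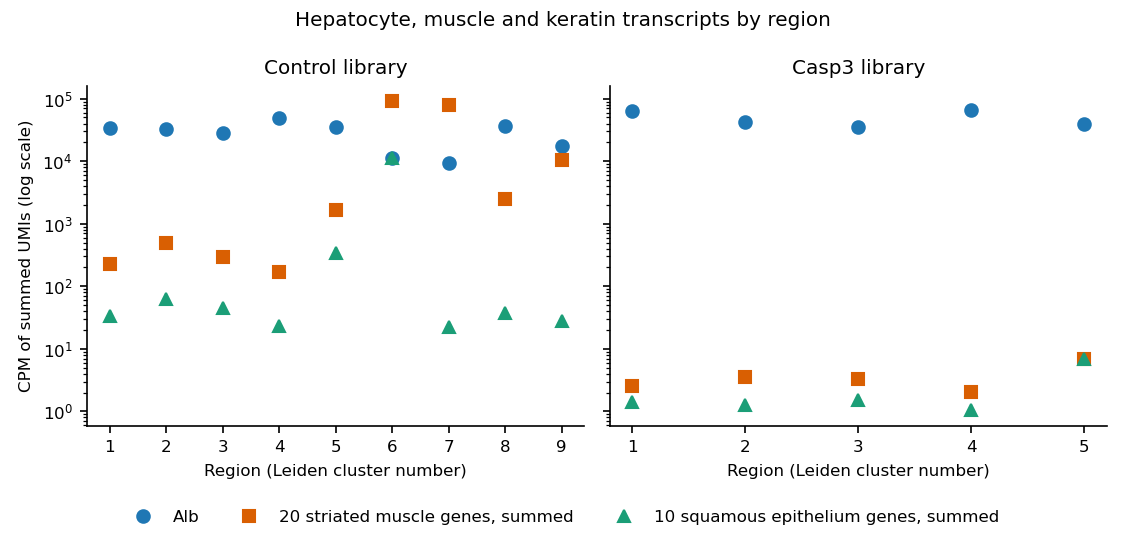
Summed CPM (log axis) of Alb, of 20 striated muscle genes and of 10 squamous epithelium genes in each region of the Control (left) and Casp3 (right) library, 1 library per group, no error bars. Striated muscle genes reach 90244 CPM in Control region 6 and 79235 CPM in region 7, where Alb is lowest, and lie between 2.07 and 3.55 CPM in regions 1 to 4 of Casp3.

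The comparison of the 2 livers asks how the liver differs between the animal labelled Casp3 and its Control on a high-fat diet. The Casp3 liver carried less RNA of the genes that coat and fill lipid droplets, of acute phase proteins and of interferon-induced genes. It carried more RNA of portal-side hepatocyte genes, metallothioneins, clock genes and genes of the unfolded protein and integrated stress responses. In the liver regions, 175 of 4394 genes with a mean of at least 20 CPM were at least 2-fold higher in Casp3 and 156 at least 2-fold lower. Over all spots the counts were 191 and 228 of 4466, and 110 of those 4466 genes were at least 5-fold higher in the 3 muscle and keratin regions than in the rest of Control. These counts describe 2 sections and are not counts of genes that respond to the manipulation. The median gene lay at -0.10. TMM scaling moved all ratios by 0.20 in the liver regions and by 0.27 over all spots, and the counts became 249 higher and 103 lower, and 311 higher and 158 lower.

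Among single genes, the highest ratio was that of Mup11 (ENSMUSG00000073834, GRCm38.p6 chromosome 4, 60658466 to 60662432), a major urinary protein, which went from 13.7 CPM in Control to 4695 CPM in Casp3, a log2 ratio of 8.43 (8.33 to 8.53). Serpina3c, a serine protease inhibitor (chromosome 12, 104146907 to 104153929), had 0.496 and 40.1 CPM (6.34, 5.81 to 6.92). Serpina1e, an alpha-1-antitrypsin gene (chromosome 12, 103946931 to 103956897), had 340 and 9766 CPM (4.84, 4.82 to 4.87). These genes have close paralogs, and the summed log2 ratio was 0.09 over the 22 Mup genes, 0.67 over the 5 Serpina1 genes and -0.09 over the 10 Serpina3 genes. The metallothioneins Mt2 and Mt1, which bind zinc and copper, stood at 4.36 (4.33 to 4.39) and 3.14 (3.13 to 3.16). Genes at least 5-fold higher in the 3 muscle and keratin regions than in the rest of Control were left out of this ranking. Among the genes ranked, the others of the 15 highest were Gm43305 (3.63), Gm49980 (3.51), Phf11c (3.48), the uridine phosphorylase gene Upp2 (2.95), Ppargc1a (2.91), Etnppl (2.85), Csrnp1 (2.72), Map3k5 (2.71), the chemokine gene Cxcl1 (2.66) and the histone methyltransferase gene Setdb2 (2.66). Ppargc1a, a coactivator of gluconeogenesis and mitochondrial biogenesis (chromosome 5, 51454249 to 52115853), had 6.43 and 48.2 CPM.

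The ranking of the lowest ratios in the liver regions also leaves out genes at least 5-fold higher in the muscle and keratin regions. Striated muscle genes left out this way stood lower than those ranked: 12 with a mean of at least 5 CPM had a median of -9.85. Among the genes ranked, the lowest ratios belonged to Cfd, which encodes complement factor D (44.7 and 0.469 CPM, -6.57, -7.14 to -6.06), and to the cyclin gene Ccnf (-5.77, -6.21 to -5.36). Apoa4, an apolipoprotein gene (chromosome 9, 46240844 to 46243458), had 1378 CPM in Control and 150 CPM in Casp3 (-3.19, -3.23 to -3.16). The acute phase gene Saa2 (chromosome 7, 46751833 to 46754313) had 1824 and 269 CPM (-2.76, -2.79 to -2.74). The PPAR-alpha target Cyp4a14 had 297 and 52.0 CPM (-2.52), and the fatty acid translocase gene Cd36 (chromosome 5, 17781690 to 17888959) had 144 and 31.6 CPM (-2.19). The rest of the lowest 15 among the genes ranked were the transcription factor gene Hhex (-3.09), Spon2 (-2.95), Paqr7 (-2.84), Tsc22d1 (-2.82), the water channel gene Aqp8 (-2.78), the estrogen sulfotransferase gene Sult1e1 (-2.78), Hba-a1 (-2.44), Anxa2 (-2.44) and the phosphatase gene Dusp6 (-2.24).

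Genes of fat storage were lower in Casp3. The median log2 ratio of the 20 measured lipid droplet genes was -0.86 (-0.90 to -0.83), with 13 lower and 3 higher by at least 0.32 (the threshold for every list member below), and 0 of 10000 expression-matched random lists reached a median as low. Plin2, the main droplet coat protein of hepatocytes (ENSMUSG00000028494, chromosome 4, 86626910 to 86670217), had 842 and 233 CPM (-1.85, -1.88 to -1.83), and Fitm1, a droplet assembly protein, had -1.90. In spots thinned to 4000 UMIs, Plin2 was found in 95.6% (94.8 to 96.3) of Control liver spots and 59.9% (58.3 to 61.5) of Casp3 spots, and without thinning in 97.2% and 92.2% of all spots. Pnpla2, a lipase that releases fatty acids from droplets, was among the 3 that were higher (0.95) and was picked after its value was seen.

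Genes of fatty acid synthesis and oxidation differed less. The 26 genes of fatty acid and triglyceride synthesis had a median of -0.34 in the liver regions (-0.37 to -0.32, percentile 0.64 of random lists), 14 lower and 4 higher. Fasn, fatty acid synthase (chromosome 11, 120805958 to 120825166), had 298 and 100 CPM (-1.57), and the malic enzyme gene Me1 had -1.95, while the phosphatidate phosphatase gene Lpin1 had 105 and 535 CPM (2.35). The 31 genes of fatty acid oxidation and ketone synthesis had a median of -0.25 (percentile 3.27), with the peroxisomal oxidase gene Acox1 at -0.93, Pex11a at -0.68 and Ppargc1a at 2.91. With TMM scaling these medians stayed negative in the liver regions (-0.15 and -0.056), and over all spots they went from -0.26 and -0.24 to 0.01 and 0.04. Before TMM scaling, the planned comparison over all spots placed both medians inside the central 95% of random lists (percentiles 5.34 and 4.91). Of the fatty acid synthesis genes, 12 were lower and 4 higher there. The 14 measured PPAR-alpha targets had a median of -0.63 (percentile 0.04), 12 lower and 1 higher, with Vnn1 at -1.74 and Aldh3a2 at -1.61. Their median over all spots, where muscle transcripts differed as described, was -1.06. The 25 genes of cholesterol synthesis had a median of -0.28 (percentile 5.80), and members went both ways. With TMM scaling the median was -0.079 in the liver regions, and over all spots it went from -0.20 to 0.07. Hmgcs1 had -1.37 and the desmosterol reductase gene Dhcr24 -0.99, while Hmgcr, the rate-limiting reductase, had 1.07.

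**Figure D2:**
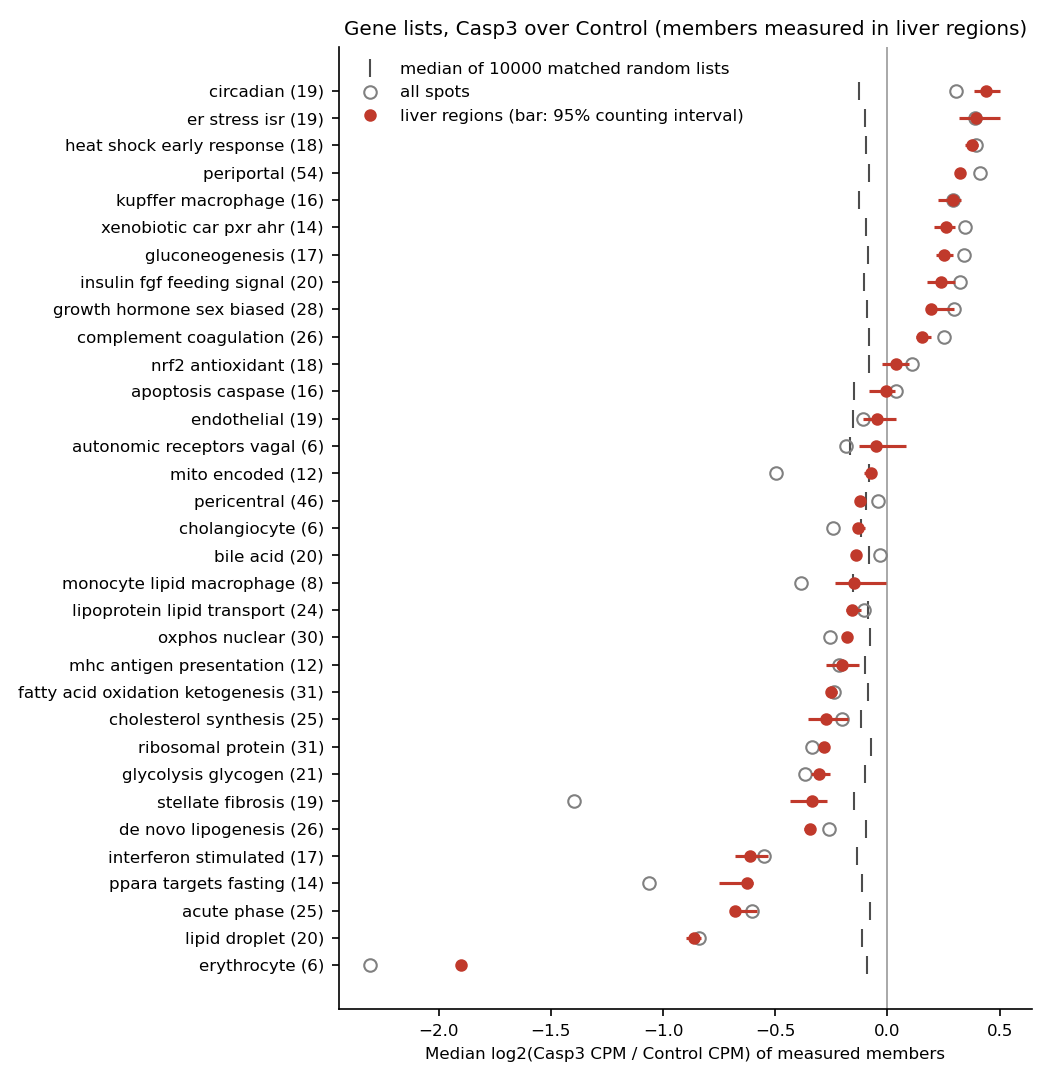
Median log2(Casp3 CPM / Control CPM) of each gene list with at least 5 measured members (number of members in brackets), in liver regions (filled, bar: 95% counting interval) and over all spots (open), 1 library per group, with the median of 10000 matched random lists (tick). Lipid droplet genes lie at -0.86 and acute phase genes at -0.68, clock genes at 0.44 and portal-side genes at 0.32, and lists that lie within 0.20 of 0 on the negative side change sign with TMM scaling.

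The position of these differences along the lobule was asked by ordering spots from the portal to the central side and comparing 5 equal ranges. Cholesterol synthesis genes increased toward the central side in Control and decreased in Casp3. Median steepness, the log2 ratio of the most pericentral to the most periportal range, was 0.33 in Control and -0.60 in Casp3 for 19 cholesterol synthesis genes. The median difference per gene was -0.83, with 16 of the 19 lower in Casp3 and 0 higher. For 24 genes of fatty acid synthesis the steepness was 0.13 and -0.51, and the median difference per gene was -0.41, with 15 lower and 0 higher. Scd1, the stearoyl-CoA desaturase gene, increased from 472 to 1278 CPM toward the central vein in Control and decreased from 759 to 358 CPM in Casp3. Fasn was near level in Control (302 and 318 CPM) and went from 178 to 56.5 CPM in Casp3. Hmgcs1, the HMG-CoA synthase gene of the sterol pathway, went from 57.5 to 122 CPM in Control and from 40.8 to 22.6 CPM in Casp3. Fdps and Idi1, which act later in that pathway, had a steepness of 0.86 and 0.46 in Control and -1.14 and -2.03 in Casp3. These lists were fixed before the data were examined, but the lists and genes singled out for their course along the lobule were picked after those values were seen.

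Along the lobule, the Casp3 to Control ratio of cholesterol synthesis genes went from 0.26 in the most periportal range to -0.67 in the most pericentral, and that of fatty acid synthesis genes from -0.03 to -0.71. Lipid droplet genes were lower in every range, from -0.37 to -0.78, and fatty acid oxidation genes lay between -0.22 and -0.27 throughout. Plin2 increased toward the central vein in Control (steepness 0.63) and was level in Casp3 (-0.05). Acute phase genes showed the opposite shift, with a median difference in steepness of 0.34 per gene, 13 of 25 higher and 1 lower. Saa1, serum amyloid A, had 5943 CPM in the most periportal and 2616 CPM in the most pericentral range of Control, and 1080 and 1699 CPM in Casp3. Pck1, the entry enzyme of gluconeogenesis, kept 2154 CPM in the most pericentral range of Casp3 against 1193 CPM in Control, and was alike at the portal side (2834 and 2886 CPM). The 16 gluconeogenesis genes as a list, with the ordering gene Sds among them, showed no such shift (median difference in steepness 0.02, percentile 31.3, 5 higher and 2 lower). Positions of spots were not used here, so the order rests on 12 marker genes and not on distance to a vein. Each library was cut at its own limits, so a range can cover unlike positions. The second range spanned pericentral shares of 42.9 to 64.0% in Control and 28.9 to 54.4% in Casp3. With pooled range limits the median difference in steepness per gene was -0.74 for cholesterol synthesis and -0.40 for fatty acid synthesis genes.

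**Figure D3:**
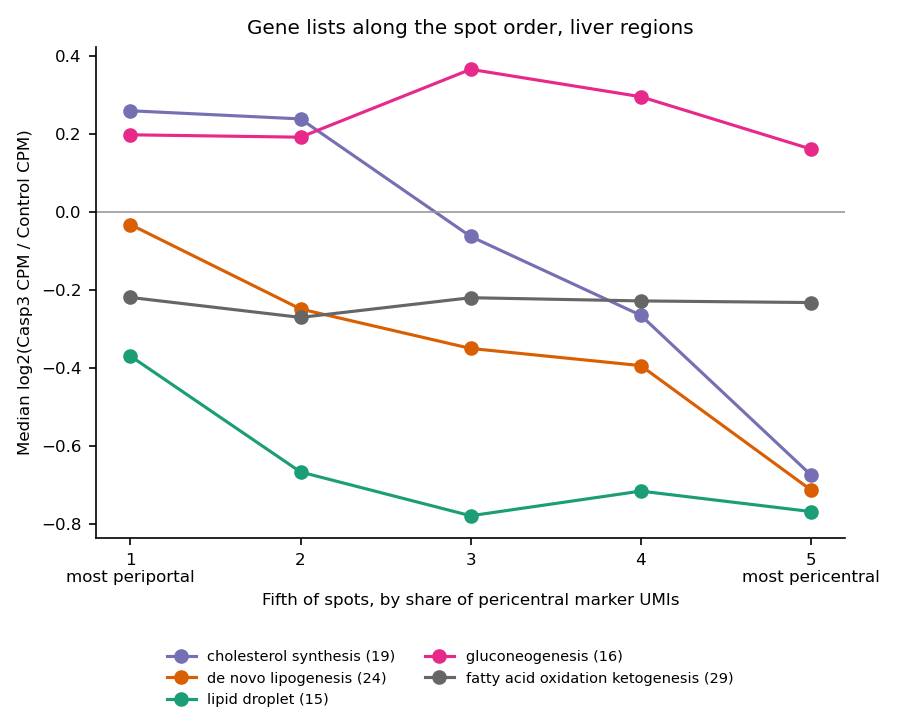
Median log2(Casp3 CPM / Control CPM) of 5 gene lists (number of members in brackets) in 5 equal ranges of spots ordered by the share of pericentral marker UMIs, liver regions, 1 library per group. Each library was cut at its own limits. The gluconeogenesis and lipid droplet lists each hold a gene used in the ordering (Sds and Hsd17b13). Cholesterol synthesis genes go from 0.26 to -0.67 and fatty acid synthesis genes from -0.03 to -0.71, while fatty acid oxidation genes stay between -0.22 and -0.27.

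**Figure D4:**
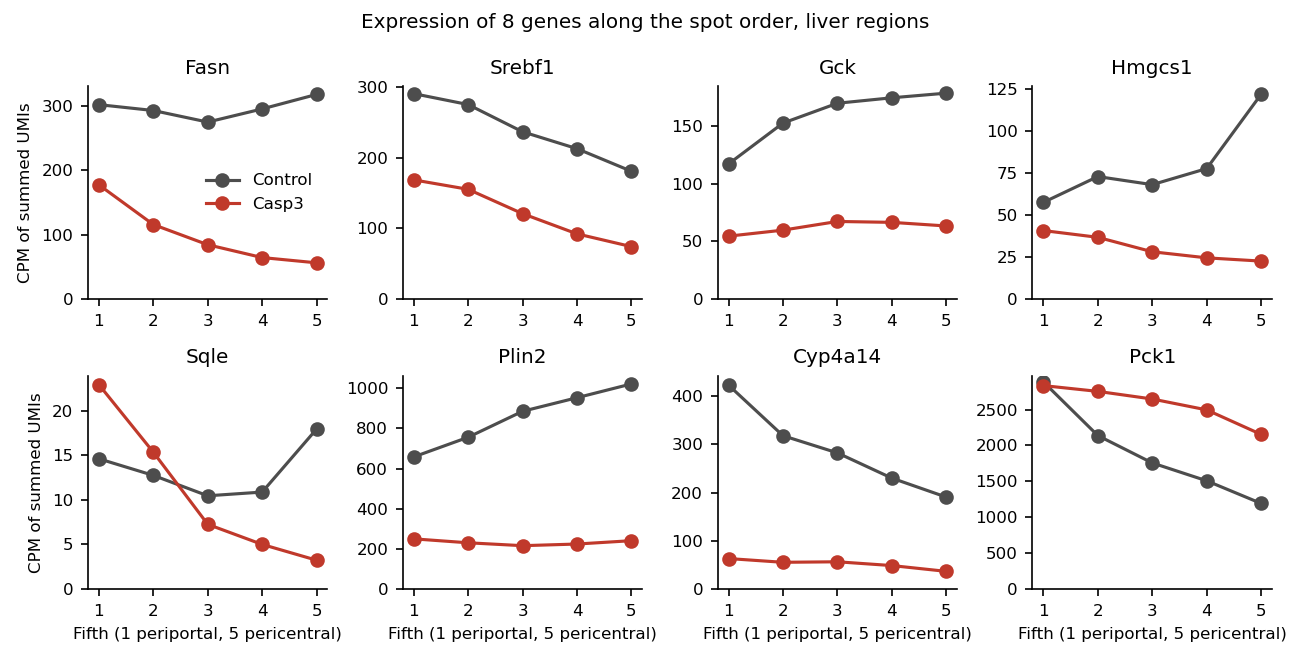
CPM of 8 genes in the same 5 ranges, from the most periportal (1) to the most pericentral (5), in Control (grey) and Casp3 (red) liver regions, 1 library per group. Hmgcs1 rises to 122 CPM at the central side of Control and drops to 22.6 CPM in Casp3, and Plin2 increases in Control only.

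Zonation of hepatocyte genes that were not used to order the spots was kept in both livers, with a shallower portal gradient in Casp3. The 46 periportal genes had a median steepness of -0.69 in Control and -0.43 in Casp3, a difference of 0.27 (0.24 to 0.30), and 18 were higher in Casp3 and 2 lower. Cps1, the first enzyme of the urea cycle, had -2.24 (-2.29 to -2.19) in Control and -1.07 (-1.09 to -1.04) in Casp3. Serpina1e had -2.35 and -0.89, and Etnppl, an ethanolamine phosphate lyase gene, had -3.84 and -2.69. The 35 pericentral genes had medians of 1.67 and 2.10, a difference of 0.43 (0.36 to 0.49), and of 1.65 and 1.89 after thinning, yet the median of the differences per gene was 0.06, with 6 higher and 8 lower, so the members did not share a direction. Aldh1a1, a retinal dehydrogenase, was steeper in Casp3 (1.06 and 2.15), and Fmo5, a flavin monooxygenase, was not (0.98 and -0.05). Over all spots Cldn2, a tight junction gene, took the place of Fmo5 among the 5 named genes (1.33 and 2.45).

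Levels of portal-side genes were higher in Casp3 and those of central-side genes were mixed. The 54 periportal genes had a median log2 ratio of 0.32 (0.30 to 0.34), 27 higher and 6 lower, above all 10000 random lists. Etnppl had 51.3 and 369 CPM (2.85), whereas Apoa4 went the other way (-3.19). The 46 pericentral genes had a median of -0.12 (percentile 35.6), 11 higher and 18 lower, and TMM scaling turned it to 0.08. Mup20 (2.28), the vasopressin receptor gene Avpr1a (2.15) and Por, the reductase that feeds electrons to cytochromes P450 (1.71), were the members farthest from 0. Gluconeogenesis genes had a median of 0.25 (percentile 99.2), 7 higher and 4 lower of 17, led by Ppargc1a (2.91), the aspartate aminotransferase gene Got1 (1.89) and the serine dehydratase gene Sds (1.39). The 21 genes of glucose use and storage had a median of -0.31, 10 lower and 4 higher, with Eno1 at -1.62, Gapdh at -1.48 and the glycogen targeting subunit gene Ppp1r3c at 1.43. Eno1 and Gapdh have many processed pseudogenes, whose share of reads is unknown.

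Most stress and clock genes that differed were higher in Casp3. The 19 genes of the unfolded protein and integrated stress responses had a median of 0.39 (0.32 to 0.50, percentile 99.96), 11 higher and 5 lower. Hspa5, the chaperone BiP (chromosome 2, 34772090 to 34776529), had 507 and 1408 CPM (1.47), the stress cytokine gene Gdf15 had 2.05 and the co-chaperone gene Dnajb9 1.36. The 19 clock genes had a median of 0.44 (percentile 99.99), 11 higher and 5 lower, led by Usp2 (3.01), Avpr1a (2.15) and the repressor gene Cry2 (1.62). Heat shock and immediate early genes had a median of 0.38 (percentile 99.93), 9 higher and 5 lower of 18, led by Junb (2.61), Dusp1 (2.16) and Fos (2.15), and with a floor of 1 CPM in place of 5 their median over all spots turned from 0.39 to -0.03. The collection times of the animals were not given in the sources used here.

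Most acute phase and interferon-induced genes were lower in Casp3. The 25 acute phase genes had a median of -0.68 (-0.68 to -0.58), 17 lower and 2 higher, and 0 of 10000 random lists reached as low. Saa1 had 4226 and 1325 CPM (-1.67) and the siderophore-binding protein gene Lcn2 -2.17, while Hamp, which encodes the iron hormone hepcidin, had 522 and 1497 CPM (1.52). The 17 interferon-induced genes had a median of -0.61 (percentile 0.04), 14 lower and 1 higher, with Ifi27l2a at -1.71 and Ifi27 at -0.92. Complement and clotting genes had a median of 0.15 (percentile 98.5), 9 higher and 3 lower of 26, with C8b at 0.81, Pros1 at 0.62 and C9 at -0.56.

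Most genes of resident macrophages that differed were higher in Casp3. The 16 macrophage genes had a median of 0.29 (0.22 to 0.33, percentile 99.87), 8 higher and 3 lower, and Marco, a scavenger receptor of Kupffer cells (chromosome 1, 120474538 to 120505024), had 11.2 and 44.6 CPM (1.99, 1.87 to 2.12). Lyz2 (-0.59) and Mpeg1 (-0.60), expressed by macrophages in general, were lower. After thinning to 4000 UMIs, the Kupffer cell marker Clec4f was found in 11.6% (10.5 to 12.8) of Control liver spots and 14.7% (13.6 to 15.9) of Casp3 spots, against 5.33% (3.57 to 7.62) in the Control muscle and keratin regions as background. Marco, added after seeing the data, was found in 3.68% (3.03 to 4.42) and 16.4% (15.2 to 17.6), with a background of 1.90%. Trem2, of lipid-associated macrophages, was found in 1.14% (0.789 to 1.59) of Control liver spots and in 1 of 3741 Casp3 spots (0.0267%, 0.0007 to 0.149), with a background of 0.381% (0.0462 to 1.37), and a second thinning found it in 5 Casp3 spots (0.134%, 0.0434 to 0.312). The neutrophil gene S100a8 was found in 1.77% (1.33 to 2.31) and 3.31% (2.76 to 3.94), with a background of 1.14% (0.421 to 2.47).

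Col1a1, a fibrillar collagen gene of stellate cells and fibroblasts, was found in 4.82% (4.08 to 5.65) of Control liver spots and 0.962% (0.675 to 1.33) of Casp3 spots, and in 27.8% of the Control muscle and keratin regions. The 19 measured stellate cell and matrix genes had a median of -0.34 in the liver regions, inside the central 95% of random lists, and -1.40 over all spots. Of the 19, 10 were at least 5-fold higher in the muscle and keratin regions, and the 9 others had a median of -0.22, 4 higher and 2 lower. In regions called led by hepatocytes, some without a leading gene, 16 measured members lay at -0.16 (percentile 43.9), 5 higher and 5 lower. A difference beyond that of other genes was therefore not seen there, and Acta1 was still found in 22.9% of Control liver spots. In the liver regions the pericyte gene Rgs5 had 0.73, the matrix protein gene Ecm1 0.62 and Sparc -0.44. Cd79a of B cells was found in 0.401% (0.208 to 0.700) of Control liver spots and 0.0535% (0.0065 to 0.193) of Casp3 spots, with a background of 0.381%. Shares of the T cell gene Cd3e (0.201% and 0.214%) and of the bile duct gene Epcam (0.234% and 0.214%), with backgrounds of 0.762% (0.208 to 1.94) and 2.86% (1.61 to 4.67), did not differ detectably at this depth, and Krt19, another bile duct gene, was found in 1.04% (0.706 to 1.47) and 0.401% (0.225 to 0.661), with 1.14% as background. The Control shares of Trem2, S100a8, Cd3e, Cd79a, Epcam and Krt19 lay within or below the interval of their background. The background regions are not a noise floor, since they hold RNA of their own cells (Col1a1 above) and some hepatocyte RNA. Alb had 10445 CPM there and 36351 CPM in the Control liver regions. The comparison with them therefore cannot tell whether the liver shares are real or background. No share compares cell numbers, since a spot holds several cells.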

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

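Of the tests below, the count of neighbouring genes was written down before its result was seen, and the other tests, with the muscle, keratin and glucocorticoid gene lists, were chosen only afterwards.

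The median steepness along the lobule had opposite signs in the 2 libraries, at 0.1 or more in each, for 3 of the fixed lists, and these differences between the libraries were not tested across animals. Casp3 minus Control was -0.94 for cholesterol synthesis genes, -0.63 for fatty acid synthesis genes and 0.22 for heat shock and immediate early genes. In the last list Fos, Egr1 and Nr4a1, picked after their values were seen, had a steepness of -2.19, -1.18 and -1.40 in Control and of -0.22, -0.09 and 0.50 in Casp3.

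Transcripts outside the liver comparison were seen in the 3 Control regions that were left out of it. Striated muscle genes summed to 82315 CPM there, squamous epithelium genes to 4805 CPM and smooth muscle genes to 326 CPM, against 449, 66.6 and 9.55 CPM in the other Control regions and 3.08, 1.39 and 3.56 CPM in Casp3.

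The first pattern is the muscle and keratin RNA of the Control section, where Acta1, Mb and Ckm reached 15881, 10224 and 10098 CPM in those regions, and no gene of the 3 lists reached 5 CPM in Casp3. Expression of these genes by Control hepatocytes would leave hepatocyte RNA at its level in the same spots, but 5 of 5 hepatocyte markers (Alb, Apoa1, Ttr, Serpina1c and Trf) were more than 2-fold lower there. Their median log2 ratio to the liver regions was -1.48, as a second tissue within the spots would give. A candidate explanation is therefore another tissue, with striated muscle and squamous epithelium, on or in the Control section. Which tissue it was, and whether it lay on the slide or was attached to the organ, stays open, since images and positions were not used here, and a link to the group was not tested.

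The second pattern is the lower RNA of lipid droplet genes in Casp3. It is not explained by the other tissue in Control, since the median stayed at -0.85 in regions not led by muscle, keratin or other non-hepatocyte markers. Those regions, some without a leading gene, still held 280 CPM of striated muscle genes in Control, against 82315 CPM in the 3 regions left out. Nor does the scaling explain the lower RNA, since the median stayed at -0.67 with TMM factors in the liver regions. Whether the state of the animals at collection contributed stays open. In Casp3, 13 of 14 measured glucocorticoid-induced genes were higher, with a list median of 1.10, including Fkbp5 (12.2 and 69.6 CPM). This list was chosen after seeing the data, and its test could speak against this explanation but not for it. With 1 animal per group, feeding, stress and time of day cannot be told apart from the group for these genes. An effect of the difference in genotype that the labels give stays open and untested.

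The third pattern is the very large ratios of single genes such as Mup11, Serpina1e and Serpina3c. For reads divided differently among paralogs, the summed CPM of 1 of the 3 families (Serpina1) differed by more than 1.5-fold in the direction of its named member, but this test decides nothing, since a difference in the named member alone would alter the sums only 1.13-fold (Mup), 1.37-fold (Serpina1) and 1.004-fold (Serpina3), so paralog assignment cannot be told apart from a difference in single members without reads. For strain haplotypes of the mixed B6 and 129S background, 6 of 55 genes at least 4-fold apart had another such gene of another name family within 1 Mb (Cfd and Midn, Phf11c and Setdb2, Tedc2 and Ccnf), and 10 had one of any name, adding Serpina1e with Serpina3c and Mt1 with Mt2, a count added after seeing the first, where random draws gave for both a median of 6 and an upper limit of 12 for the central 95%. The bound set in advance against this explanation, a count at or below the random median, was met, but that bound was wrong by design, since a variant that alters 1 gene needs no neighbour, and the pair Phf11c and Setdb2 had been noticed before. Haplotypes therefore cannot be told apart from the group for these genes, and both may contribute.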

How the results depend on the processing

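No paired analysis was possible because each group held 1 animal, and leaving out a library could not be run for the same reason. The restriction to liver regions, to regions led by hepatocytes and to liver spots under 0.1% muscle and keratin UMIs, the combination of liver regions with TMM factors, and all values of steepness per list member were added after seeing the data. Among medians of the 6 main lists, 30 values under alternatives stayed within the counting interval and 48 moved beyond it, among 2-fold counts 19 stayed and 7 moved, and among shares 46 and 18. Of the other list medians 184 stayed, 256 moved and 5 reversed, and of gene ratios 745, 876 and 10. A value counts as reversed when its sign differs from a main value that lay outside the central 95% of random lists, or for a gene at a log2 ratio of at least 0.32 beyond counting error. Without that condition the sign also differed for 7 medians of the main lists, 38 other list medians, 11 gene ratios and 6 steepness differences per list member. Of region counts 4 stayed and 2 moved, of steepness differences in the main comparison 8 and 6, of others 16 and 12, and of those per list member 102 stayed, 46 moved and 7 reversed. Periportal genes stayed higher and lipid droplet, acute phase and interferon genes stayed lower in Casp3 under every alternative run. TMM and median-of-ratios factors shift every gene alike, which is the cause of the moves they give. For other moves and reversals the cause was not tested. Depth limits the shares, which count a marker only where the 4000 UMIs kept per spot include it.

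With TMM factors over all spots, 311 genes were 2-fold higher, and medians were 0.011 (fatty acid synthesis), 0.036 (fatty acid oxidation), 0.57 (macrophage), -1.12 (stellate), 0.23 (pericentral) and 0.69 (periportal), while nuclear-encoded respiratory genes reversed to 0.019. With median-of-ratios factors these were 310 genes, 0.0095, 0.034, 0.57, -1.12, 0.23 and 0.68, and 0.017 for the respiratory genes. Without mitochondrially encoded genes the medians were -0.29 (fatty acid synthesis), -0.26 (fatty acid oxidation), -1.23 (stellate) and -0.067 (pericentral). With the stricter spot filter they were -0.29 (fatty acid synthesis), -0.065 (pericentral) and 0.38 (periportal). With equal weight per spot they were -0.22 (fatty acid oxidation), 0.20 (macrophage), -1.64 (stellate), -0.070 (pericentral) and 0.50 (periportal).

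With a lower gene floor 307 genes were 2-fold higher and 648 lower, and heat shock genes reversed to -0.031. With a floor of 50 CPM the counts were 120 and 93, and medians were -0.14 (fatty acid synthesis), -0.47 (stellate) and 0.38 (periportal). Without regions led by the fixed non-hepatocyte markers, but with the muscle and keratin regions of Control kept, macrophage genes had 0.37 and periportal genes 0.38.

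In the liver regions medians were -0.34 (fatty acid synthesis), -0.34 (stellate), -0.12 (pericentral) and 0.32 (periportal), the pericentral steepness difference was 0.43, and shares in Control were 4.82% (Col1a1) and 0.234% (Epcam). In regions led by hepatocytes medians were -0.34 (fatty acid synthesis), -0.26 (fatty acid oxidation), -0.16 (stellate), -0.11 (pericentral) and 0.29 (periportal). In liver spots under 0.1% muscle and keratin UMIs they were -0.33 (fatty acid synthesis), -0.27 (stellate), -0.095 (pericentral) and 0.29 (periportal). In liver regions with TMM factors 103 genes were 2-fold lower, and medians were -0.15 (fatty acid synthesis), -0.056 (fatty acid oxidation), 0.49 (macrophage), -0.14 (stellate), 0.077 (pericentral) and 0.52 (periportal), with reversals to 0.12 for mitochondrially encoded and 0.019 for nuclear-encoded respiratory genes. In these 4 settings, in the same order, Fabp5 reversed from -0.53 over all spots to 0.37, 0.55, 0.50 and 0.57, and Lpl from -1.96 to 0.62, 0.97, 0.95 and 0.81. Each of these settings leaves out Control regions where Fabp5 had 170 CPM and Lpl 675 CPM, against 16.2 and 12.1 CPM in the liver regions of Control. In the last 2 settings mt-Nd4l reversed from -0.68 to 0.013 and 0.11.

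The steepness difference of pericentral genes, 0.57 over all spots, was 0.41 after thinning, 0.43 with a floor of 5 CPM and 0.37 with pooled range limits, and that of periportal genes, 0.27, was 0.32 after thinning and 0.34 with that floor. The median difference per member reversed for mitochondrially encoded genes from -0.08 over all spots to 0.0449 in the liver regions, 0.0921 with the 4-gene order, 0.0217 with 3 ranges and 0.0921 after thinning. For nuclear-encoded respiratory genes it reversed to 0.0062 after thinning and 0.0031 with pooled limits, and for pericentral genes to -0.023 with pooled limits.

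Unthinned shares over all spots, with the muscle and keratin regions of Control included, in Control and Casp3, were 31.8% and 41.3% (Clec4f), 2.97% and 0.764% (Trem2), 6.14% and 10.0% (S100a8), 0.655% and 0.815% (Cd3e), 0.846% and 0.306% (Cd79a), 20.9% and 3.85% (Col1a1), 2.05% and 1.22% (Epcam), 3.74% and 1.22% (Krt19), 97.2% and 92.2% (Plin2), and 12.3% and 44.1% (Marco). They were higher than thinned shares over all spots because spots were deeper. For Col1a1 in Control that thinned share was 8.25%, so its distance from the share in liver regions also reflects the regions included. Casp3 had 11 regions at resolution 1 and 11 regions came from joint clustering, in which each of the 11 held at least 90% of its spots from 1 library.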

Other observations

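All gene lists in this part were fixed before their values were seen, and the genes named for steepness were picked afterwards.

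Red cell and neutrophil genes differed between the livers. The 6 measured red cell genes had a median log2 ratio of -1.90 in the liver regions and -2.30 over all spots, with Hbb-bt at -2.80 and Hbb-bs at -2.08, and haemoglobin genes gave 0.131% of UMIs in Control and 0.0310% in Casp3. The 3 measured neutrophil genes had a median of 0.99, with the histidine decarboxylase gene Hdc at 1.22, S100a8 at 0.99 and the calprotectin subunit gene S100a9 at 0.85. The 3 measured B and plasma cell genes had a median of -0.88, with the immunoglobulin genes Ighm, Igkc and Igha at -1.92, -0.88 and -0.48, but in regions led by hepatocytes 2 of them were measured at a median of -0.47, inside the central 95% of random lists (percentile 18.4). None of the 19 T and NK cell genes or the 24 nerve and glia genes reached 5 CPM. The 8 measured genes of monocytes and lipid-associated macrophages had a median of -0.15, 0.05 with TMM factors and -0.39 over all spots, with the chemokine gene Ccl9 at 0.76. The 19 endothelial genes had -0.05 (0.15 with TMM factors), with Mrc1 at 0.77 and Eng at -1.07, and the 6 bile duct genes -0.13 (0.07), with Tstd1 at 0.68.

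Hepatocyte programmes under hormones and drugs also differed. Growth hormone and sex-biased genes had a median of 0.19 (percentile 99.73), 13 higher and 7 lower of 28, with the male-biased Mup20 at 2.28. Cyp2b9, a female-biased P450 gene, stood at -1.94. Insulin and feeding genes had 0.24, with Igfbp2, an insulin-like growth factor binding protein gene, at 273 and 1328 CPM (2.28). Drug metabolism genes had 0.26, with Cyp1a2 at 1.19 and Cyp2b10 at 15.1 and 36.0 CPM. Bile acid genes had -0.14 (0.06 with TMM factors), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.22 and the 12-alpha-hydroxylase gene Cyp8b1 at -1.21. Lipoprotein and lipid transport genes had -0.16 (0.04), with the cholesterol exporter gene Abca1 at 0.75, and antioxidant genes, metallothioneins included, had 0.04.

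Antigen presentation genes had a median of -0.20 in the liver regions, with the class II gene H2-Ab1 at 0.68 and the peptide transporter gene Tap1 at -1.07. Over all spots their median was -0.21, and 0.06 with TMM factors. Along the lobule their steepness was 0.08 in Control and -0.43 in Casp3, with 5 of 12 lower and 0 higher. Cd74, the invariant chain, had 60.3 CPM in the most periportal and 81.5 CPM in the most pericentral range of Control, and 120 and 65.5 CPM in Casp3. Ribosomal protein genes had a median of -0.28, 14 lower and 0 higher of 31, with Rps2 at -1.45 and Rpl10 at -0.96, genes with many pseudogenes. Nuclear-encoded respiratory genes had -0.18 (0.02 with TMM factors). Mitochondrially encoded genes had -0.075 (0.12) in the liver regions, 2 lower and 1 higher (mt-Nd3, at 0.71) of 12, but -0.49 over all spots, 11 lower and 0 higher. The 4 measured nuclear-retained RNAs had 0.06 in the liver regions and -0.27 over all spots, with Neat1 at 0.90.

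Cell death genes had a median of -0.01 (0.19 with TMM factors), with the survival gene Bcl2l1 at 1.75 and the arrest gene Cdkn1a at 1.12. The 4 measured proliferation genes had -0.18 (0.02), with Ccnd1 at -0.82. The 6 measured receptor genes of autonomic transmitters had -0.05 (0.15), with the adrenergic receptor gene Adra1b at -0.19 (0.0080).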
